A study of Mus musculus with 2 samples.

How the data were processed

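The samples were 2 pools of embryonic mouse hindbrain at day 16.5, both of 1 group, and each gave 1 library. Per the labels, RNA was extracted with the Ambion mirVana kit, RNA longer than 200 bases was used, 10 ng of RNA entered each library, spike-ins were added, and a linked protocol covers the SMARTer Ultra Low kit. The number of embryos in the pool of replicate 1 is not given in the sources used here.

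The authors quantified each replicate separately against the mm10 assembly with GENCODE M4, per the deposited notes. The quantification tool and its version are not given in the sources used here, and the column names are of the kind that RSEM writes. Per the file headers, each gene and transcript has an expected count, which is the number of reads the authors' model assigns to it and need not be whole. The deposited TPM values correct these for effective length and scale them to a fixed total over all features, spike-ins included. Deposited FPKM values were used in an alternative. Interval bounds on TPM were deposited as well, which are treated as scores here, and their confidence level is not given in the header. The deposited percent of a gene's TPM taken by each transcript was used for isoforms. TPM lay within its interval for 95.4% of genes above 1 TPM in replicate 1 and 95.7% in replicate 2. The exceptions include some of the most abundant genes, such as Tuba1a. Its TPM in replicate 1 was 14366, above an interval of 13998 to 14079. For all transcripts over 300 bases, length exceeded effective length by 99. Whether counting used strand is not given, so antisense partners such as Xist and Tsix cannot be told apart.

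Each gene file lists 69691 features, of which 43346 have Ensembl gene identifiers. Names, gene types and positions came from GENCODE M21 on GRCm38, the same build as mm10, joined on identifiers without version. There were 42462 matches and 884 identifiers without one, which held 0.173% of counts in replicate 1 and 0.171% in replicate 2. List members without a match, such as Rmst and Snhg1, are not analysed here. Values of some genes that belong to the lists and pairs, and enter their counts, are not reported here. Features with a bare number as identifier held 4e-05% of counts in replicate 1.

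Expected counts were rounded to whole numbers and scaled with TMM in edgeR 4.0.16 (R 4.3.3), with spike-ins kept out of library sizes. Log2 ratios of replicate 2 over replicate 1 used a prior count of 0.5 and genes with a mean of 1 TPM or more. The biological coefficient of variation is the square root of edgeR's common dispersion, with an intercept alone, over genes with at least 10 counts in both libraries. Genes at 0 were compared against a floor of 3 counts in the library. DESeq2 1.42.0 gave alternative size factors. Tables were handled in Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1.

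A gene was called detected at 1 TPM in both libraries. The median level of each of 34 lists was set against 10000 random lists of its size. A list stood apart between replicates when the median ratio of at least 5 members lay outside percentiles 2.5 to 97.5 of 10000 random lists. These percentiles describe the 2 libraries and are not tests over samples. The random lists were drawn from protein-coding genes in 20 bins of mean TPM, a detail chosen after the data were examined. A gene pair was called when the deposited intervals did not overlap in either library. The design called for intervals at a level of 95%, which the headers do not state.

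The groups, tests, lists, pairs, isoform genes and the main alternatives were chosen before the data were examined. The genes named are up to 4 members of each list with the highest mean TPM and, where informative, the lowest, every Hox gene, both genes of each pair, the 15 protein-coding genes with the highest mean TPM outside the mitochondrial genome, the 10 genes each way with the largest ratio between libraries among those whose intervals do not overlap, and the isoform genes. Ptf1a, Dbh, Top2a, Aqp4, Fezf2, Six3 and Scn10a, and in the closing section Drd2, Ppp1r1b, Tbr1, Apoe and Pax8, fall outside that rule and were named after their values were seen. Alternatives covered detection minimum, unit, scaling, prior count, filters, gene type, coding transcripts and each replicate left out.

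The ratio step was tested on simulated counts for 43346 genes with 200 changed. It recovered 100% of genes changed 4-fold and 53% of genes changed 2-fold past the 2-fold limit, and 0.278% of unchanged genes with at least 100 counts passed it. The simulated coefficient of variation of 15.7% came back as 15.7%, and as 17.8% with the changed genes present. With ratios shuffled among genes, 2 of 32 lists stood apart. In the closing section, pseudogene sequences were compared with protein-coding transcripts by shared 31-mers, and intervals of medians came from 2000 bootstrap draws.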

Results

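RNA longer than 200 bases, from extracts labelled as total RNA, was sequenced from the hindbrain of B6NCrl mouse embryos at day 16.5 of development. The hindbrain gives rise to the medulla, pons and cerebellum. There were 2 biological replicates of a single group, each a pool of tissue from male and female embryos, and replicate 2 came from 37 embryos. The deposited gene values summed to 42467811 expected counts in replicate 1 and 42017008 in replicate 2. Counts above 0 were listed for 24201 genes in replicate 1 and 24483 in replicate 2. With 1 group there is no contrast between conditions, and the smallest p that permuting 2 libraries can give is 0.5, so no p is given. The questions the design allows are which genes the tissue expressed, how related genes compared within it, and how far the 2 pools differed. Levels below are TPM, a length-corrected relative abundance, as the mean ± SD of n = 2 replicates unless a replicate is named, and positions are on GRCm38.

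The most abundant protein-coding gene outside the mitochondrial genome was the alpha-tubulin Tuba1a (ENSMUSG00000072235.5, chromosome 15, 98949837 to 98953703), at 14378 ± 17.1 TPM. Among the 15 such genes with the highest mean were also the adult alpha-globin Hba-a2 at 6263 ± 885 TPM, the imprinted gene Nnat at 5355 ± 12, the microtubule regulator Stmn1 at 4741 ± 7.59 and the beta-tubulin Tubb2a at 3056 ± 286. They also held the ferritin light chain gene Ftl1 at 4543 ± 145 TPM, the ubiquitin gene Ubb at 3720 ± 40.9, the cyclophilin gene Ppia at 3577 ± 189 and the chaperone gene Hspa8 at 2796 ± 61.7. At 1 TPM or more in both replicates were 13630 of 21474 protein-coding genes (63.5%), of which 1667 reached 100 TPM and 70 reached 1000 TPM. In 31 of 34 gene lists at least 50% of the measured members reached 1 TPM in both replicates. The median levels of 10 lists lay above the central 95% of random lists, 23 lay within it and 1, with a median of 0 TPM, was ranked below. Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical copies, so the split of counts within each set is uncertain.

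Hox genes of the anterior paralog groups were expressed and those of the posterior groups were mostly not detected. Hox genes encode transcription factors that set position along the body axis. Of the 15 genes of groups 1 to 5, 13 reached 1 TPM in both replicates, led by Hoxb5 (chromosome 11, 96303336 to 96306121) at 106 ± 7.72 TPM, Hoxa5 at 80.5 ± 11.8, Hoxc4 at 49.8 ± 1.97 and Hoxd3 at 38.4 ± 2.67. The exceptions were Hoxb1 at 0.235 ± 0.0778 and Hoxd1 at 1.03 ± 0.141 TPM. Of the 8 genes of groups 6 to 8, 7 reached that level, led by Hoxb6 at 43.3 ± 1.97 and Hoxb7 at 26.1 ± 2.31 TPM. Of the 16 genes of groups 9 to 13 only Hoxb9 did, at 4.39 TPM in replicate 1 and 1.21 in replicate 2. The median of that list was 0 TPM. No random list can have a median below 0, so its rank at the bottom was fixed by that value.

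**Figure D1:**
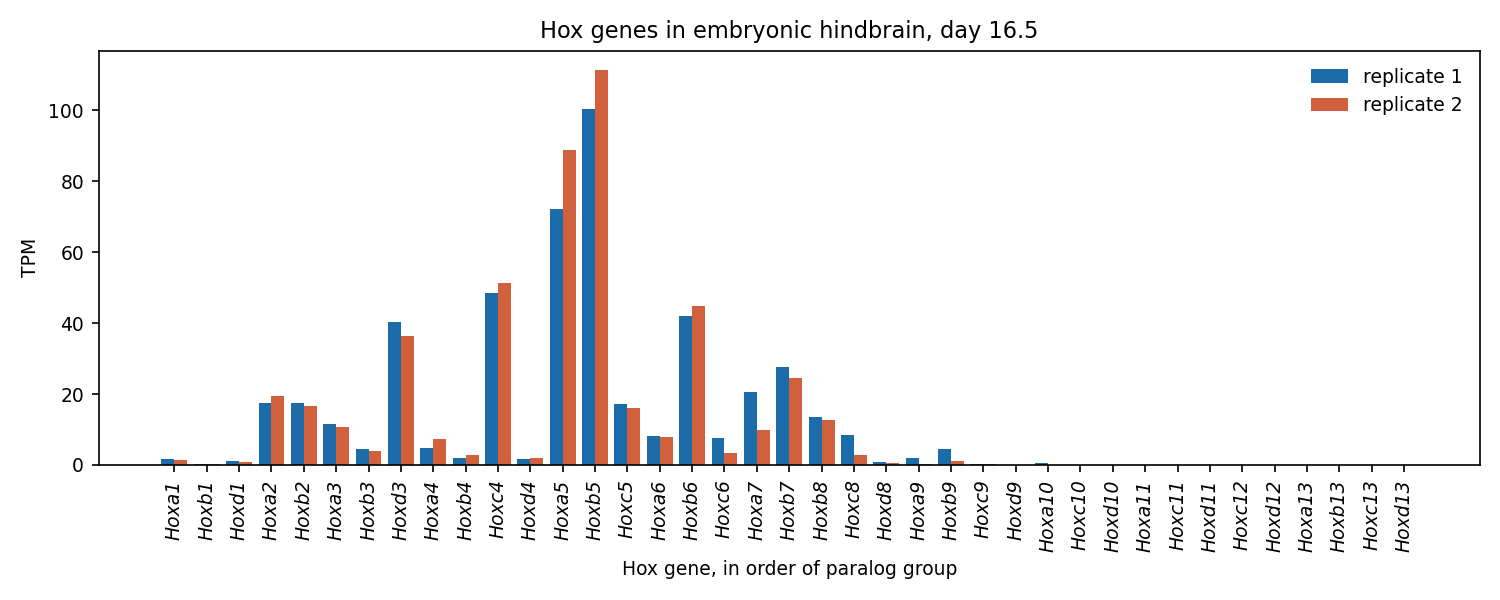
TPM (vertical axis) of each Hox gene (horizontal axis, ordered by paralog group), with 1 bar for each replicate. Hoxb5 has the tallest bars, at 100 TPM in replicate 1 and 111 TPM in replicate 2, and the bars of groups 9 to 13 lie below 5 TPM.

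Forebrain transcription factors had a median of 1.71 TPM in replicate 1 and 0.05 TPM in replicate 2, where most were near the detection limit. Of the 11 with at least 10 counts in a replicate, 9 were over 2-fold higher in replicate 1. Of 13 such genes only Neurod6 reached 1 TPM in both replicates, at 30.7 ± 3.86 TPM. Dlx1 had 7.94 TPM in replicate 1 and 0.07 in replicate 2, Fezf2 had 1.84 and 0.05, and Six3 had 1.79 and 0.05. The midbrain and isthmus list had 6 of 10 members at 1 TPM, led by Gbx2 at 29.1 ± 1.70 TPM and Otx2 at 19.4 ± 3.13. Otx2 is also a member of the choroid plexus list.

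Cerebellar lineages were well represented. All 18 genes of the granule cell lineage reached 1 TPM in both replicates, with a median of 25.2 TPM, including Meis1 at 154 ± 0.0566 TPM, Zic4 at 54.1 ± 2.88, Mycn at 50.5 ± 3.98 and Pax6 at 35.4 ± 1.77. Of 12 Purkinje cell genes 11 did, with Pcp4 at 381 ± 43.4 TPM, Dab1 at 70.2 ± 8.70, Foxp2 at 35.9 ± 8.93 and Rora at 32.6 ± 1.03, while Skor2 stood at 0.685 ± 0.134 TPM. Rhombic lip and ventricular zone factors were lower, with 7 of 10 at 1 TPM and a median of 2.63 TPM. Atoh1, the factor of the rhombic lip, had 9.97 ± 3.30 TPM and Ptf1a, the factor of the ventricular zone, 1.35 ± 0.0354 TPM.

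Genes of neurons in general had a median of 287 TPM, and all 15 reached 1 TPM in both replicates. Tubb3 stood at 1599 ± 43.2 TPM, the growth cone gene Gap43 at 1406 ± 108 and Stmn2 at 1157 ± 120. Transmitter genes followed. All 14 genes of GABA and glycine transmission were detected, with a median of 49.2 TPM, and 11 of 12 glutamatergic genes, with a median of 24.5 TPM. The vesicular glutamate transporter Slc17a6 had 91.7 ± 5.44 TPM, the GABA-synthesising enzyme gene Gad1 106 ± 4.82 and the glycine receptor gene Glra2 48.7 ± 0.170.

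Genes of neuromodulatory and motor neurons of the brainstem were detected at lower levels, well within the range of random lists. Among random lists of protein-coding genes the serotonergic list stood at percentile 62.9, the noradrenergic list at 46.2 and the cholinergic and motor list at 45.4. All 10 serotonergic genes were detected, with a median of 9.05 TPM, among them Tph2, the rate-limiting enzyme of serotonin synthesis, at 10.3 ± 1.70 TPM and the serotonin transporter gene Slc6a4 at 10.2 ± 2.13. Of 7 noradrenergic genes 6 were detected, with a median of 4.90 TPM, including Dbh at 4.49 ± 0.587 and Th at 8.21 ± 0.735 TPM. Of 12 cholinergic and motor neuron genes 10 were detected, with a median of 5.48 TPM, including Prph at 53.8 ± 17.0 and Slc18a3 at 20.3 ± 2.67 TPM. Ddc belongs to both monoamine lists.

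Progenitor and glial genes were expressed beside the neuronal ones. The radial glial gene Fabp7 had 2120 ± 394 TPM and Vim 353 ± 50.6 TPM, and 12 of 13 progenitor genes were detected, with a median of 11.9 TPM. All 16 cell cycle genes were detected, with a median of 31.5 TPM, including Cdk1 at 71.7 ± 3.85 and Top2a at 32.5 ± 7.07. All 10 astrocyte genes were detected, with a median of 56.2 TPM, led by Aldoc at 402 ± 103 and Slc1a3 at 218 ± 5.23 TPM. All 7 oligodendrocyte precursor genes were detected, with Olig1 at 144 ± 21.6 and Pdgfra at 16.1 ± 1.25 TPM. Of 8 myelin genes 6 were detected, with Cnp at 66.1 ± 7.20 and Mbp at 36.0 ± 2.02 TPM, while Mobp was at 0.175 ± 0.00707 TPM.

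Genes of other cell types that the dissected tissue could hold were also detected, some of them no higher than random genes. Of 12 choroid plexus genes 11 were detected, led by Ttr, the thyroxine carrier of that epithelium, at 1599 ± 249 TPM. All 12 endothelial and pericyte genes were detected, with Cldn5 at 105 ± 0.919 TPM, and all 12 microglial genes, with C1qb at 43.5 ± 2.32 TPM. Of 10 red blood cell genes 9 were detected and of 10 meningeal and fibroblast genes 8, with Col3a1 at 205 ± 70.5 TPM. Of 9 Schwann cell and sensory neuron genes 7 were detected, with a median of 4.19 TPM, while Scn10a and Prdm12 lay below 1 TPM. Skeletal muscle and cartilage genes had 5 of 12 members at 1 TPM in both replicates, with a list median of 7.06 TPM in replicate 1 and 0.685 TPM in replicate 2. Among random lists of protein-coding genes the Schwann and sensory list stood at percentile 41.3 and muscle and cartilage at 41.1, against 82.9 for endothelium and pericytes, 78.8 for choroid plexus and 76.8 for microglia, while the red blood cell and meningeal lists lay above the central 95%.

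The remaining lists covered cell state and RNA type. All 16 imprinted genes were detected, with a median of 98.2 TPM, or 59.4 TPM counting protein-coding transcripts alone, including Meg3 at 1994 ± 114 and Ndn at 1221 ± 25.5 TPM. Of 11 hypoxia and glycolysis genes 10 were detected, with Ldha at 772 ± 30.9 TPM, and of 10 immediate early genes 8, with a median of 3.67 TPM. Histone variants with polyadenylated messages had a median of 200 TPM over 8 genes, and 12 of 20 replication-dependent histone genes were detected, with a median of 2.33 TPM, though reads shared among near-identical histone genes make single values uncertain. All 7 measured long noncoding RNAs were detected, with Malat1 at 4079 ± 199 TPM. Of 10 abundant small or non-polyadenylated RNAs 5 were detected, with Rn7sk at 164 ± 10.6 TPM, and Rn7s1 and Rn7s2, near-identical copies of the signal recognition particle RNA, at 10230 ± 225 TPM each.

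Within the tissue, 18 of 20 gene pairs fixed in advance differed in both replicates, as judged by deposited intervals that did not overlap. Slc17a6 was 103-fold above Slc17a7, the other vesicular glutamate transporter (log2 ratio 6.68 ± 0.34, SD, n = 2). The chloride exporter gene Slc12a5 was 8.87-fold above the importer gene Slc12a2, and the glycine receptor gene Glra2 was 22.1-fold above Glra1. Grin2b was 4.60-fold above Grin2a (log2 ratio 2.20 ± 0.46), and Gad1 was 3.11-fold above Gad2. Adult globins exceeded embryonic ones, Hbb-bt by 109-fold over Hbb-y (log2 ratio of Hbb-y over Hbb-bt -6.77 ± 0.75) and Hba-a1 by 329-fold over Hba-x. The log2 ratio of Hba-x over Hba-a1 was -8.36 ± 1.02, with -7.64 in replicate 1 and -9.08 in replicate 2, so leaving out either library moved that fold by over 1.5 times.

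Further pairs compared genes of early and late neurons and of glia. Dcx was 3.54-fold above Rbfox3, Nefm was 27.2-fold above Nefh and Map1b was 2.31-fold above Map2. Slc1a3 was 15.1-fold above Slc1a2, Mbp was 2.24-fold above Pdgfra, Dnmt3a was 26.6-fold above Dnmt3b and Igf2 was 10.2-fold above Igf1. Dlg4 was 1.85-fold above Dlg3. Cdk1 and Cdk5 did not differ by this rule, nor did Nes and Gfap, whose log2 ratio was 2.07 in replicate 1 and -0.026 in replicate 2. Counting protein-coding transcripts alone, Gad1 over Gad2 became 0.83 on the log2 scale, against 1.64 from all transcripts, and Grin2b over Grin2a became 4.58. The same change put Hba-x over Hba-a1 at -5.95, Slc12a2 over Slc12a5 at -2.43, Igf2 over Igf1 at 2.58 and Cdk1 over Cdk5 at -1.24.

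**Figure D2:**
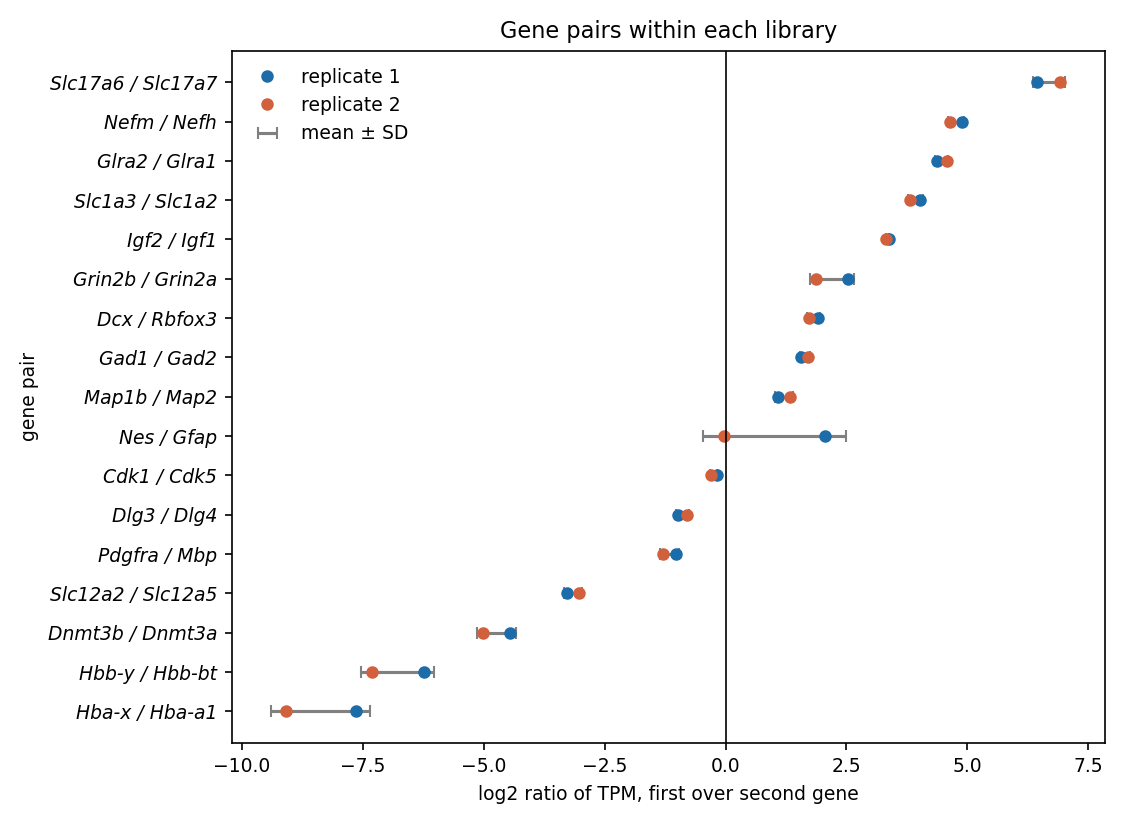
Log2 ratio of TPM of the first over the second gene (horizontal axis) for the gene pairs named in the text (vertical axis), with a point per replicate and a bar for the mean ± SD. Slc17a6 over Slc17a7 lies farthest right, at 6.68, and Nes over Gfap has points on both sides of 0.

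The 2 pools were close for most protein-coding genes. Across 15910 genes with a mean of 1 TPM or more, Pearson's r of log2(TPM + 1) between replicates was 0.979 and Spearman's rho 0.980, correlations across genes, which are not independent replicates. Among 13843 protein-coding genes 98.5% lay within 2-fold. The biological coefficient of variation was 15.7%, and the chi-square of the counts against counting error alone was 24.0 per degree of freedom over 17947 genes. That the libraries are separate biological samples rests on the labels. Over 2-fold apart were 709 genes, of which 465 were higher in replicate 2 and 244 in replicate 1. Scaling by spike-in totals, which shifts all genes by 0.44 on the log2 scale, put 814 higher in replicate 2 and 153 in replicate 1. Among protein-coding genes alone, 56 were higher in replicate 2 and 152 in replicate 1.

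Of the 32 lists compared, skeletal muscle and cartilage lay farthest toward replicate 1. The forebrain list was not among the 32, since only 4 of its members had a mean of 1 TPM. Over members with at least 10 counts in a replicate, its median log2 ratio was -5.07, against -3.23 for muscle and cartilage. The 10 genes with the largest ratio in that direction were Kera, Myog, Dlx5, Ckm, Dlx1, Tnnc2, Actc1, Sln, Myh3 and Myl1. Of these, Myog, Ckm and Myh3 belong to the muscle and cartilage list, and Dlx1 and Dlx5 to the forebrain list. Ckm (chromosome 7, 19404776 to 19422841), the muscle creatine kinase, had 29.3 TPM in replicate 1 and 0.42 in replicate 2, a 68.2-fold ratio with a counting interval of 40.5 to 125. Myog, a myogenic factor, had 189 counts against 2, a ratio of 93.1 with an interval of 25.4 to 775. Kera, a corneal proteoglycan, had 116 counts against 0. Its ratio was 38.1 with the 0 taken as 3 counts, and its counting interval began at 30.5. The muscle and cartilage list was 10.1-fold higher in replicate 1 (median log2 ratio of replicate 2 over 1 of -3.34, below all 10000 random lists), with 0 of its 10 expressed members higher in replicate 2. These intervals and floors cover counting error only.

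Of 32 lists with enough expressed members, 17 lay outside the central 95% of random lists matched on expression, where 1.6 would be expected if lists were independent, which lists of co-expressed genes are not. Across protein-coding genes the ratio also went with transcript length, with a median log2 ratio of 0.12 in the shortest 10% and -0.12 in the longest 10%, about the size of the smaller list medians. With random lists matched on length as well, 16 of the 17 lists still lay outside. On the side of replicate 1 were 10 lists. Beside muscle and cartilage these were cholinergic and motor neurons (median log2 ratio -0.48), meningeal fibroblasts (-0.46), the X-inactivation and Y-linked genes (-0.42), rhombic lip factors (-0.39), red blood cells (-0.30), endothelium and pericytes (-0.26), the cell cycle (-0.25), progenitors (-0.17) and imprinted genes (-0.090). Summed counts went the other way in 3 of these lists, with a log2 ratio of 0.16 for progenitors, 0.16 for the X and Y genes and 0.089 for imprinted genes. The most abundant progenitor gene, Fabp7, had 1841 TPM in replicate 1 and 2399 in replicate 2, and 7 of 16 imprinted genes were higher in replicate 2. Col1a1, a fibrillar collagen, was 2.54-fold higher in replicate 1, with 231 against 88.0 TPM, and embryonic Hbb-y was 2.55-fold higher, with 28.2 against 10.7 TPM. Among the sex-linked genes, Xist, with 14.4 against 18.4 TPM, was higher in replicate 2, while the Y-linked Eif2s3y, with 31.7 against 21.6 TPM, was higher in replicate 1. Of these 17 lists 7 turn sign under spike-in scaling, namely the X and Y genes, rhombic lip, red blood cells, endothelium, cell cycle, progenitors and imprinted genes, so their direction holds relative to other genes. Cholinergic and motor neurons, at -0.041, and meningeal fibroblasts, at -0.021, lay near 0 under that scaling. Of the 10 lists only muscle and cartilage, at -2.90, kept a large shift toward replicate 1.

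On the side of replicate 2 were 7 lists. These were replication-dependent histones (0.23), astrocytes (0.21), microglia (0.17), oligodendrocyte precursors (0.16), choroid plexus (0.16), glutamatergic transmission (0.15) and GABA and glycine transmission (0.14). Of the 10 astrocyte genes 8 were higher in replicate 2. Gfap (chromosome 11, 102887336 to 102900912), the astrocytic intermediate filament, was 3.36-fold higher, with 13.0 against 4.03 TPM, and the water channel gene Aqp4 was 2.29-fold higher, with 26.8 against 12.1 TPM. Taking TPM ratios in place of scaled counts, the GABA and glycine, precursor and choroid plexus lists no longer lay outside the random range. The precursor list also fell inside it at a mean of 5 TPM or with random lists from all genes, and the histone list, the exception among the 7, when transcript length was matched.

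**Figure D3:**
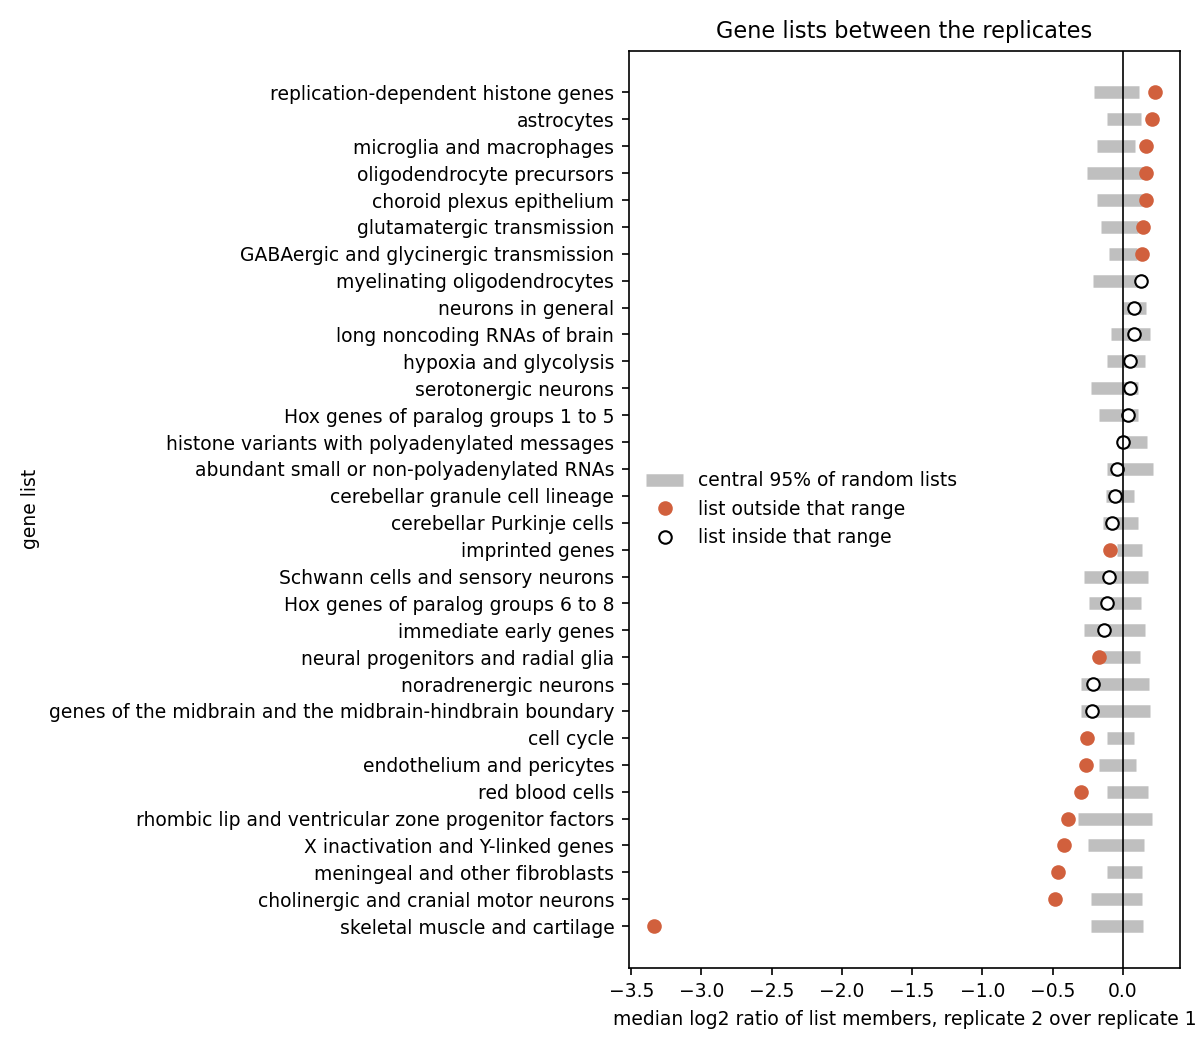
Median log2 ratio of replicate 2 over replicate 1 (horizontal axis) for each gene list (vertical axis), with a grey bar for the central 95% of random lists matched on expression. Filled points are the 17 lists outside their bar, and the skeletal muscle and cartilage list lies farthest left, at -3.34.

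Processed pseudogenes, which are copies of messages inserted in the genome, were higher in replicate 2. Their median log2 ratio was 1.06 over 589 genes, and 303 were over 2-fold higher in replicate 2 against 12 in replicate 1. For protein-coding genes the median was -0.0084. All 10 genes with the largest ratio toward replicate 2 were processed pseudogenes, including Gm9726 with 194 against 12.1 expected counts and Gm11993 with 77.4 against 5.36. Reads that match both a pseudogene and its parent gene are divided by a model, so single pseudogene values are uncertain.

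**Figure D4:**
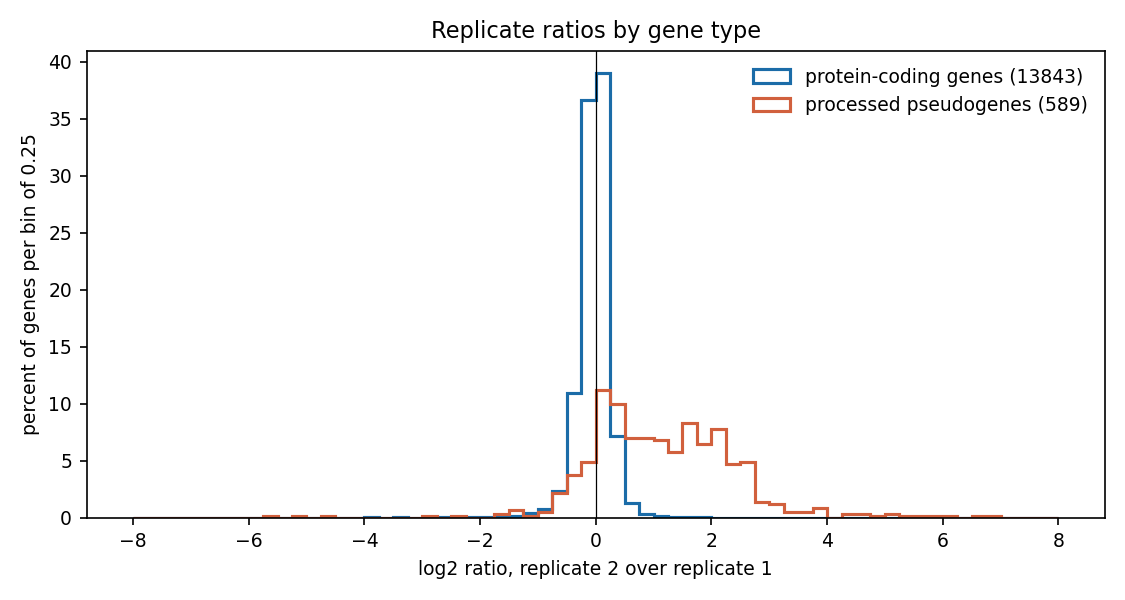
Percent of genes per bin (vertical axis) by log2 ratio of replicate 2 over replicate 1 (horizontal axis, bins of 0.25), for genes with a mean of 1 TPM or more. Protein-coding genes center near 0 and processed pseudogenes spread to the right, with a median of 1.06.

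At transcript level the replicates mostly shared the major isoform. Of 7132 genes with at least 2 annotated transcripts and a mean of 10 TPM, 6629 (92.9%) had the same leading transcript in both. The leading transcript held a median of 68.0% of its gene. Mapt, which encodes tau, had 45.6% ± 0.884 in Mapt-205 and 34.4% ± 1.42 in Mapt-204 (SD, n = 2). Cdc42 was divided between Cdc42-201 at 51.9% ± 1.81 and Cdc42-202 at 48.1% ± 1.81. Some leading transcripts were annotated as not coding, as in Gria2, where the retained-intron transcript Gria2-206 held 41.9% ± 0.891, and in Gad1, where the processed transcript Gad1-206 held 61.0% ± 2.04. The leading transcript of Foxp2 differed between replicates, with Foxp2-201 at 33.6% in replicate 1 and 27.7% in replicate 2 and Foxp2-207 at 22.9% and 31.5%.

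Protein-coding genes took most of the counts in both libraries. They held 92.9% ± 0.192 of expected counts (SD, n = 2), long noncoding genes 1.74% ± 0.132, genes of the mitochondrial genome 1.68% ± 0.268 and pseudogenes 1.41% ± 0.205. Nuclear ribosomal RNA genes held 6.1e-05%. Spike-in RNAs held 2.18% in replicate 1 (95% Wilson interval 2.17 to 2.18) and 1.59% in replicate 2 (1.59 to 1.60), intervals that cover counting error only, and 79 of 96 listed had a count in both. The spike-in total relative to the gene total was 1.36-fold higher in replicate 1.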

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

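Leaving processed pseudogenes out, the use of all genes for random lists, list medians under spike-in totals, and the 2-fold rule for pairs with posterior means or coding transcripts were tests chosen only after the data were seen. No paired analysis was possible because there is only 1 group. Detected genes numbered 10870 at a minimum of 5 TPM, 14426 at 0.5 TPM, 12954 by FPKM and 13845 by posterior mean TPM, and ranged from 13764 to 13918 with 1 replicate left out, while called pairs stayed at 17 to 19, and lists apart between replicates at 15 to 18. The coefficient of variation was 17.5% over genes with any count, 12.2% at 100 counts or more, 14.5% as the median tagwise value, 13.0% in protein-coding genes and 13.4% without processed pseudogenes. Genes over 2-fold apart numbered 2677 at a mean of 0.1 TPM, 147 at 10 TPM, 208 among protein-coding genes and 394 without processed pseudogenes, where the number of genes compared differs by construction. Isoform agreement was 90.4% at a mean of 1 TPM and 95.6% at 50 TPM. In TPM in place of counts, protein-coding genes held 82.3% and spike-ins 4.52%. The units differ by the correction for effective length, which raises the share of short features. Without 1 replicate the protein-coding share ranged from 92.7% to 93.0% and the spike-in share from 1.59% to 2.18%. Lists with at least 50% of members detected numbered 24 at a minimum of 5 TPM, 32 at 0.5 TPM, 29 with protein-coding transcripts alone, and 31 to 33 with 1 replicate left out. Scaling by spike-in totals turned the sign of 7 list medians, to 0.055 for rhombic lip, 0.27 for progenitors, 0.19 for the cell cycle, 0.15 for red blood cells, 0.18 for endothelium and pericytes, 0.024 for the X and Y genes and 0.35 for imprinted genes, because it shifts all genes by 0.44. No other called list median or gene pair changed sign under the alternatives run for it. Of the other values, 46 moved by more than the spread between replicates and 6 list results no longer stood apart under an alternative. Depth limits genes near 0, where a few counts set the ratio.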

Other observations

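The test of diluted neural RNA was chosen only after its result was seen. The olfactory receptor genes were chosen for the test of genomic DNA after the pseudogene values had been seen and before their own were looked at. The other lists used in this part were written after the fixed lists had been seen and before their own values were looked at, except that Six3 and Dnmt3b had been seen. Bone and tendon genes outside these lists, such as Ibsp and Tnmd, had also been seen among those higher in replicate 1.

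Genes of some other regions of the nervous system were also mostly higher in replicate 1. Of 11 forebrain factors with at least 10 counts in a replicate, 11 were higher in replicate 1 and 9 by over 2-fold. Of 6 striatal genes 5 were higher in replicate 1, with Drd2 at 4.95 against 1.90 TPM and a median log2 ratio of -0.54. The most abundant of them, Ppp1r1b, had 6.53 against 7.85 TPM, and Six3 is counted among the forebrain factors as well. Of 6 cortical genes 5 were higher in replicate 1, with Tbr1 at 1.15 against 0.38 TPM and a median of -0.42. Of 4 hypothalamic genes with counts 2 were, with a median of 0.045 and a log2 ratio of summed counts of 0.24, toward replicate 2. None of these lists was tested against the muscle list. The posterior genes Hoxa9, at 2.00 against 0.41 TPM, and Hoxc8, at 8.32 against 2.70 TPM, were also higher in replicate 1. Of 10 genes of earlier embryonic stages 7 were higher in replicate 1, with a median log2 ratio of -0.31. Of 5 epidermal genes with counts 1 was higher in replicate 1, and the median was 0.30.

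Muscle, cartilage and forebrain genes were higher in replicate 1, and tissue from the margins of the dissection may have been carried into that pool. Midbrain and isthmus genes did not share a shift of that size. The 10 with counts had a median log2 ratio of -0.22, against -5.07 for forebrain factors, and 7 of them were higher in replicate 1. That list lay within the range of random lists. The 10 bone and tendon genes with counts had a median log2 ratio of -0.79 (95% bootstrap interval -2.06 to -0.096), which lies between the bounds set for and against carried-over tissue, so it cannot be told apart from other origins. Of the 11 genes in those lists 6 reached 1 TPM in replicate 2 as well, and the most abundant, Spp1, had 19.7 against 12.5 TPM. Visceral organs are argued against as a source of RNA or reads. Summed counts of 32 liver, heart, lung, kidney and intestine genes had a log2 ratio of 0.066 (-0.22 to 0.20), and 0.016 without Pax8, which took most of those counts. That result covers these organs only. RNA or reads from libraries of other tissues, forebrain and skeletal muscle included, were not tested. No biological explanation of this difference was tested.

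Processed pseudogenes were higher in replicate 2, and a candidate explanation is that reads of parent genes were placed on similar copies more often in that library. The 432 pseudogenes that share at least 50% of their 31-mers with protein-coding transcripts had a median log2 ratio of 1.24, the 118 that share 5 to 50% had 0.77 and the 39 that share under 5% had 0.063, a difference of 1.18 between the first and last (95% bootstrap interval 0.81 to 1.52). That interval treats pseudogenes as independent, yet many are copies of the same parent gene and some have identical counts, so it may be too narrow. The rise did not simply follow identity, since the 75 that share all 31-mers had a median of 0.35, and 50 of these lay under 0.5. Genomic DNA that covers silent genes as it covers pseudogenes is argued against by 1020 olfactory receptor genes. Their mean was 0.00712 TPM in replicate 1 and 0.00615 in replicate 2, so it did not rise. That gain was -0.000418 times the median gain of 2.32 TPM at pseudogenes (95% bootstrap interval -0.00115 to 0.000315). The pseudogenes were those with a mean of 1 TPM or more, while the receptor genes had no such filter, so the sets were chosen differently. Genomic DNA that entered the sets unevenly was not tested. What would place reads differently was not tested, so the candidate stays a hypothesis.

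Astrocyte genes were higher and embryonic globins lower in replicate 2, and the pool of replicate 2 may have been slightly older. A separate list of 17 later astrocyte genes had a median log2 ratio of 0.33, past the bound of 0.25 set for a later stage, though its bootstrap interval of 0.14 to 0.43 includes that bound. Of these genes 14 were higher in replicate 2, with Apoe at 1167 against 705 TPM. That list tests astrocyte content more directly than age, so a pool with more astrocytes at the same age stays open. Dilution of neural RNA in replicate 1 would move astrocyte and neuronal genes alike. The median of the 27 genes of both astrocyte lists exceeded that of the pan-neuronal list by 0.24 (95% bootstrap interval 0.074 to 0.36). That value cannot decide, because 10 of those genes are the astrocyte list whose rise is to be explained. The median of the 17 later genes alone exceeded it by 0.25 (0.051 to 0.38), which dilution alone would not give for these genes. Both comparisons were chosen after the medians were known.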
